A study of Mus musculus with 6 samples.

How the data were processed

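RNA sequencing was run on 6 mouse cells from 3 mice, named 1157, 1168 and PDGF1 in the labels. Each mouse gave 1 circulating tumor cell (CTC), a tumor cell taken from blood, and 1 tumor cell. The source label calls each CTC a single cell and leaves that word out for the tumor cells, while the series text counts 6 single cells in all. Per the labels' protocols, cells were lysed in buffer with a mild detergent, and mRNA was copied into double-stranded cDNA and transcribed back into RNA in repeated rounds, a linear amplification meant to keep transcripts in proportion. Stranded mRNA libraries were then made with a TruSeq kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols.

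The deposited table gave FPKM, fragments scaled by transcript length and by the mapped fragments of the library, for 45038 rows, per the name of the authors' table. The submitters' processing notes name STAR 2.4.2a, Cufflinks 2.2.1 and the mouse genome build GRCm38. How reads that match several genes were treated is not given in the sources used here, which matters for ribosomal protein genes, since these have many near-identical pseudogenes. Read counts were not analysed here and the depth of each cell is unknown, so no counting interval was computed, and a value of 0 is reported only as listed at 0. FPKM is a share of all mapped fragments weighted by gene length, so a cell whose fragments come largely from other sequence has lower FPKM for every mRNA.

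In the table, 27 rows had a gene name turned into a date and 211 rows had a name listed more than once. Both kinds were left out, which left 44804 rows. Of these, 41450 matched a gene name in GENCODE mouse release 21, an annotation on GRCm38 that supplied coordinates and gene classes. It gave 18859 protein-coding genes with a full name, and 1412 olfactory and vomeronasal receptor genes, which belong to sensory neurons of the nose and served as a measure of background.

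The groups were CTCs (3 cells) and tumor cells (3 cells), and the replicate was the mouse. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, over the 4165 genes at 1 FPKM or more in at least 3 of the 6 cells. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SEs it gave follow the variance trend over all genes rather than the spread of each gene. Differences are CTC minus tumor cell on that log2 scale, which understates the change of low genes. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The number of genes at 1 FPKM or more per cell was compared by a two-sided exact permutation test, where 3 cells against 3 cannot give a p below 0.1. A further count took genes that differed by at least 1 in the same direction in all 3 mice, where 3 pairs cannot give a p below 0.25. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

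The groups, the rule for named genes, the gene lists, the tests above and the alternatives were fixed before the data were examined, except for a second myeloid list, a rescaling over named protein-coding genes, a count of genes above the receptor level of each cell and an exact paired test of detected genes, which were added later. The rule took up to 10 genes per direction past the threshold, filled where too few passed with the genes of smallest unadjusted p whose CTC values all lay on one side of the tumor cell values. It added up to 4 members of each list by smallest p, a set of single marker genes, Xist and Y-linked genes, and the 5 genes of highest FPKM per cell. Predicted genes with no name, pseudogenes and repeated names were passed over in the first and last parts, and a few genes the rule names are not reported here. Other genes named for mouse 1168, and the 5 predicted genes summed as repeat-like signal, were chosen after their values were seen.

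Each mouse gave 1 cell of each kind, so the mouse number pairs the cells. After the group means were removed, cells of the same mouse correlated across genes at 0.178 in mouse 1157, 0.689 in mouse 1168 and 0.428 in mouse PDGF1. The CTC of mouse PDGF1 correlated with the tumor cell of mouse 1157 as well, at 0.422, so the pairing rests on the labels and not on these values. The fit with the mouse as a block was an alternative. Within 1 mouse there is no replicate, so no p is given there, and the median of a list is placed among the medians of 10000 random lists of the same size matched on mean expression, which describes those 2 libraries only.

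The limma step was tested on simulated data for the comparison of 3 CTCs with 3 tumor cells over 4165 genes. With a spread of 0.3 on the log2 scale it recovered 100% of genes changed by 2, by 4 and by 6, with 8 false calls. With the spread of these cells, whose median SD was 1.88, it recovered 0% at each of those sizes. The alternatives were other pseudocounts, filters, scalings and variance models, the block, other detection levels, and each mouse or cell left out.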

Results

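Transcripts were measured in 3 CTCs and 3 tumor cells, 1 of each from mice 1157, 1168 and PDGF1. Both cells of mouse 1168 held a broad set of transcripts, with FPKM sums of 729330 in the CTC and 616400 in the tumor cell. Their FPKM was mostly in named protein-coding genes, at 85.2% and 72.1%. In the other cells that share was 51.7% in the CTC and 17.6% in the tumor cell of mouse 1157, and 11.9% and 23.2% in those of mouse PDGF1. In mouse 1157 the row of highest FPKM was a different short RNA gene in each cell. The miRNA gene Gm26154 alone took 29.2% in the CTC, and the snRNA gene Gm26487 alone took 41.6% in the tumor cell. A set of 5 predicted genes, Gm10800, Gm10801, Gm21738, Gm10718 and Gm10717, of which the first 2 lie side by side on chromosome 2, took 66.2% of the FPKM in the CTC and 48.6% in the tumor cell of mouse PDGF1. In mouse 1168 they took 1.56% and 3.02%.

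The first comparison asked whether CTCs and tumor cells hold transcripts of different numbers of genes. The CTC had fewer genes at 1 FPKM or more than the tumor cell in 3 of 3 mice, with 2883 against 4095 in mouse 1157, 9741 against 11287 in mouse 1168 and 1493 against 3041 in mouse PDGF1. The means were 4706 ± 4416 (SD, n = 3) in CTCs and 6141 ± 4488 (SD, n = 3) in tumor cells, a difference within the spread between mice (two-sided exact permutation test, p = 0.5, smallest possible 0.1). Within mice the differences were -1212, -1546 and -1548, a mean of -1435 ± 193 (SD, n = 3 pairs), and the exact paired test gave p = 0.25, the smallest that 3 pairs allow. Counted at 5 FPKM the mean difference turned to 41.7 genes more in CTCs, and at 10 FPKM to 224 more (two-sided exact permutation test, p = 0.9 and 0.7). In mouse PDGF1 the CTC stayed lower, with 458 against 754 genes at 5 FPKM and 244 against 364 at 10 FPKM. Named protein-coding genes above the 99th percentile of receptor genes in the same cell were more in the CTC in 3 of 3 mice, with 2481 against 1397 in mouse 1157, 10149 against 8958 in mouse 1168 and 429 against 269 in mouse PDGF1. That percentile was lower in each CTC than in its tumor cell. It lay at 0.775 against 2.025 FPKM in mouse 1157, 0.129 against 1.23 in mouse 1168 and 2.71 against 7.16 in mouse PDGF1. The direction of the mean difference thus depended on the level of detection.

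**Figure D1:**
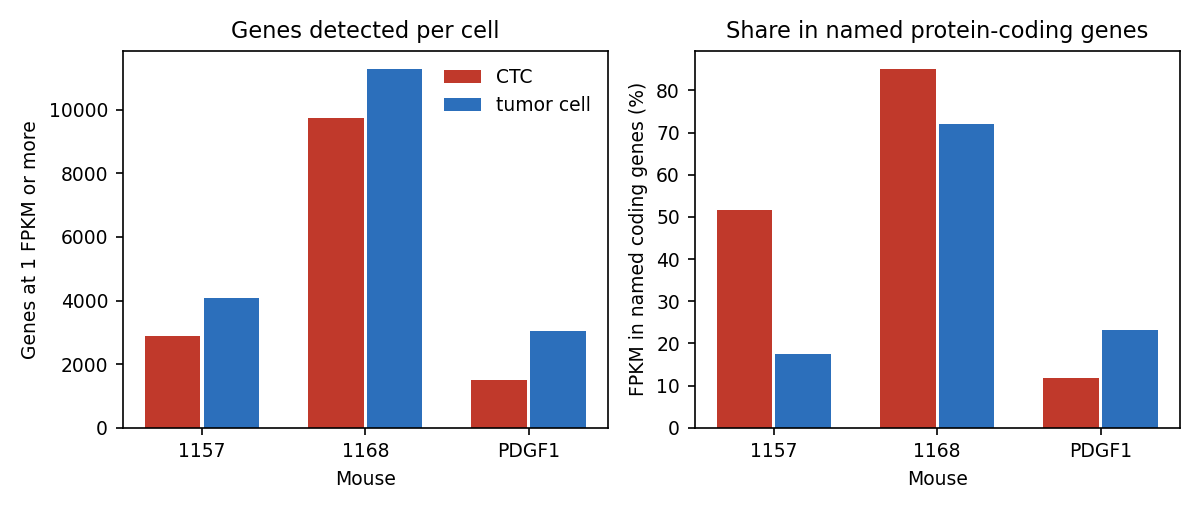
Bars show, for the CTC (red) and the tumor cell (blue) of each mouse, the number of genes at 1 FPKM or more (left) and the percent of FPKM in named protein-coding genes (right), 1 cell per bar. Both cells of mouse 1168 stand above the other 4 cells, with 9741 and 11287 genes.

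The second comparison asked which genes differ between CTCs and tumor cells over the 3 mice. No gene passed the threshold. Among genes lower in all 3 CTCs than in any tumor cell, Irf5, a transcription factor of the interferon response, was at 0.127, 0.308 and 0.0910 FPKM in the CTCs of mice 1157, 1168 and PDGF1 and at 11.7, 2.76 and 6.82 in their tumor cells. Dsn1, a kinetochore protein, was at 0.119, 0.0335 and 0.134 against 1.88, 9.58 and 1.90. Supv3l1, a mitochondrial RNA helicase, went the other way, at 20.5, 75.6 and 19.3 FPKM in CTCs against 0.148, 13.7 and 0.0570.

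By limma, 0 of 4165 genes passed, and 7 had an unadjusted p under 0.05, all lower in CTCs. The log2 difference was -2.62 for Irf5 (SE 1.48, adjusted p = 0.9999, limma), -2.02 for Dsn1 (SE 1.03) and 3.62 for Supv3l1 (SE 3.13). Others lower in all 3 CTCs than in any tumor cell were Errfi1, an inhibitor of the EGF receptor, at -1.75, Ehbp1l1 at -1.85, Clmp, an adhesion molecule, at -1.66, Zfp141 at -1.51, Arhgef39 at -1.45, Rsph1 at -1.40 and Fam184b at -1.13. In the tumor cell of mouse PDGF1, Irf5, Dsn1, Errfi1, Ehbp1l1, Clmp, Arhgef39 and Fam184b lay under the 99th percentile of receptor genes, 7.16 FPKM. Dsn1, Ehbp1l1 and Fam184b also lay under it in the tumor cell of mouse 1157 (2.025), and Fam184b in that of mouse 1168 (1.23). There they cannot be told from background. With CTC values under 1, these genes met the filter only through the tumor cells. Ptpn7, a tyrosine phosphatase, at 1.93 and the kinase Map3k1 at 0.80 were higher in all 3 CTCs. CTCs lay fully above the tumor cells for 11 genes and fully below for 54, together 1.56% of genes, where chance gives 10% for 6 exchangeable cells, and less for cells that share levels within a mouse.

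With the mouse as a block, limma called 1 gene, Snora2b, a small nucleolar RNA on chromosome 15 from 98526346 to 98526482 (minus strand, GRCm38), inside the gene Kansl2 and overlapping one of its annotated exons on the same strand. It was listed at 0 in all 3 CTCs and at 156 FPKM in the tumor cell of mouse 1157, 8.36 in that of mouse 1168 and 4.80 in that of mouse PDGF1. The last value lay under the 99th percentile of receptor genes in that cell, 7.16 FPKM. Snora2b is short, so few fragments can give such values, and read counts are unknown. The blocked log2 difference was -4.35 (SE 0.918, adjusted p = 0.00906, limma), and reads of Kansl2 cannot be told from its own. That SE does not come from the spread of this gene over the 3 mice. The p thus does not measure how far the mice agree on its size. With the block and quantile normalization together no gene passed (smallest adjusted p = 0.896).

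Among the gene lists, cytosolic ribosomal protein genes stood higher in CTCs over the 3 mice. Within each mouse their median lay inside the central 95% of random lists matched on mean expression. The percentiles were 24.6 in mouse 1157, 56.0 in mouse 1168 and 27.2 in mouse PDGF1. Where a cell holds low values for most genes, as in mice 1157 and PDGF1, that mean largely sets the difference. The central 95% of random medians in mouse 1157 ran from 4.315 to 5.991. The percentiles of mice 1157 and PDGF1 thus cannot decide whether the list stood apart. Of 75 members tested, 62 had a positive and 13 a negative difference, with a median of 1.12. In mouse 1157 the median was 4.98, with Rpl4 at 3668 FPKM in the CTC against 7.55 and Rps19 at 2837 against 12.4. In mouse 1168 it was 0.63, with Rpl4 at 1964 against 754, and in mouse PDGF1 it was -1.78, with Rps19 at 7.09 against 46.9. The list was 1 of 24 tested to pass (camera, adjusted p = 0.00260), and the call was lost with an estimated correlation (adjusted p = 0.9997 with an estimated correlation) and by fry (p = 0.785). No member passed over all genes, and 0 passed adjusted over the list alone. Without the CTC of mouse 1157 the adjusted p was 0.772, without its tumor cell 0.451, and without both the direction turned, at 0.730.

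Nuclear-encoded subunits of the respiratory chain were positive in 44 of 56 tested members. Cox8a was at 3469 FPKM in the CTC of mouse 1157 against 7.30 in its tumor cell, at 2136 against 1199 in mouse 1168, and at 2.16 against 3.88 in mouse PDGF1. Within mice the median of the list was 1.14 in mouse 1157 (percentile 13.8 of random lists), 0.78 in mouse 1168 (percentile 93.9) and -0.77 in mouse PDGF1 (percentile 89.7). The limit on such percentiles in mice 1157 and PDGF1 holds here too. The list missed the threshold (camera, adjusted p = 0.0889) and passed with the mouse as a block (adjusted p = 0.0324), which made 2 lists in place of 1. It also passed under other alternatives, with adjusted p (camera) from 0.000204 without the tumor cell of mouse 1168 to 0.0440 with a pseudocount of 0.1. It did not pass with quantile normalization (0.567), without mouse 1157 (0.730) or without mouse 1168 (0.277). It had an adjusted p = 0.9997 with an estimated correlation and p = 0.851 by fry, both without the block. The mitochondrially encoded genes were negative in 12 of 12 members (adjusted p = 0.291). In mt-Cytb the CTC and the tumor cell had 2.73 and 4.37 FPKM in mouse 1157, 2039 and 3425 in mouse 1168, and 2.80 and 341 in mouse PDGF1. Within mouse 1157 the list went the other way, with a median of 1.53 and 5 of 8 measured members higher in the CTC by at least 1, among them mt-Nd2 at 31.2 against 3.16. Markers of oligodendrocyte progenitors, the dividing precursors of myelin-forming cells, were positive in 7 of 7 tested members (adjusted p = 0.203), and interferon-stimulated genes were negative in 4 of 5 (adjusted p = 0.203). Within mice the progenitor list had a median of 0.33 in mouse 1157, 1.60 in mouse 1168 and -1.90 in mouse PDGF1, where only 3 members were measured. Without mouse 1168 its adjusted p was 0.891 (camera).

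The other 19 lists had adjusted p between 0.672 and 0.999. Wnt ligands, receptors and transducers were negative in 5 of 7 members and targets of beta-catenin, the transcriptional arm of Wnt signalling, positive in 4 of 6 (both adjusted p = 0.672). Neural and glioma stem cell genes were negative in 8 of 13 (adjusted p = 0.793). For each of these 24 lists, 0 members passed adjusted over the list alone.

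The third comparison asked which genes differ the same way within each mouse. At a log2 difference of at least 1, 14 genes were higher and 30 lower in the CTC of all 3 mice, 44 in total. Swapping the labels of the 2 cells of mouse 1157 gave 32, of mouse 1168 gave 50 and of mouse PDGF1 gave 79, so the true labels did not give the highest count. Across genes, which are not independent replicates, the differences correlated at 0.0860 between mice 1157 and 1168, at -0.111 between 1157 and PDGF1, and at -0.0190 between 1168 and PDGF1.

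Within mouse 1168, whose cells held the most genes, the CTC had higher FPKM of oligodendrocyte progenitor genes than the tumor cell. Nkx2-2 and Olig2, transcription factors of that lineage, were at 27.2 and 42.5 FPKM in the CTC against 0.752 and 10.3. The proteoglycan genes Cspg4, Cspg5 and Bcan were at 17.5, 117 and 17.3 against 1.71, 23.7 and 3.78. Of 19 members measured, 13 were higher in the CTC by at least 1 on the log2 scale and 3 lower, among them Gpr17, at 0.113 against 10.2 FPKM, and Dll3, at 0.143 against 8.43. The median of 1.60 lay at percentile 100 of random lists. Genes of PDGF and growth factor receptor signalling had a median of 0.63, at percentile 98.6. The ligand Pdgfb was at 5.62 FPKM against 0.424, its family receptor Pdgfra at 5.28 against 1.42, and Etv5, a factor induced by receptor signalling, at 21.8 against 2.15, while the receptor Met was lower, at 0.0666 against 8.64.

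The tumor cell of mouse 1168 had higher FPKM of myeloid, interferon and mesenchymal genes. Of 18 microglia and macrophage genes measured, 16 were lower in the CTC by at least 1 and 0 higher (median -3.19). The lysozyme gene Lyz2 was at 174 FPKM in the CTC against 1202 in the tumor cell, the protease gene Ctss at 19.4 against 672, the adaptor gene Tyrobp at 28.4 against 346 and the lipid receptor gene Trem2 at 0.0975 against 26.3. Leukocyte markers shared by all lineages were at 1 FPKM or more for 14 of 20 in the tumor cell and 1 of 20 in the CTC, with Cd52 at 0.377 against 203. Interferon-stimulated genes had a median of -2.73, with 17 of 21 lower by at least 1. Irf7 was at 0.0403 against 22.5 FPKM and Rtp4 at 0.0230 against 61.8.

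Mesenchymal genes had a median of -2.32 in mouse 1168, with 26 of 32 lower in the CTC by at least 1 and 0 higher. The calcium-binding S100a6 was at 122 FPKM in the CTC against 1861, the adhesion receptor Cd44 at 8.55 against 74.4, the secreted Spp1 at 0.182 against 167 and the smooth muscle gene Tagln at 0.0910 against 29.2. Vim, an intermediate filament, was high in both, at 586 and 870. Extracellular matrix genes (median -1.45), immediate early and dissociation stress genes, markers of mature oligodendrocytes (-1.60) and of pericytes and fibroblasts (-1.65) were lower as well. These lists and the microglia, leukocyte and interferon lists lay at or below percentile 0.020 of random lists. Lists that follow RNA quality differed too: mitochondrially encoded genes had a median of -0.71 (percentile 0.015) and housekeeping genes of -0.22 (percentile 0.040). Each of these differences within mouse 1168 compares 1 library with 1 other and has no replicate check.

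**Figure D2:**
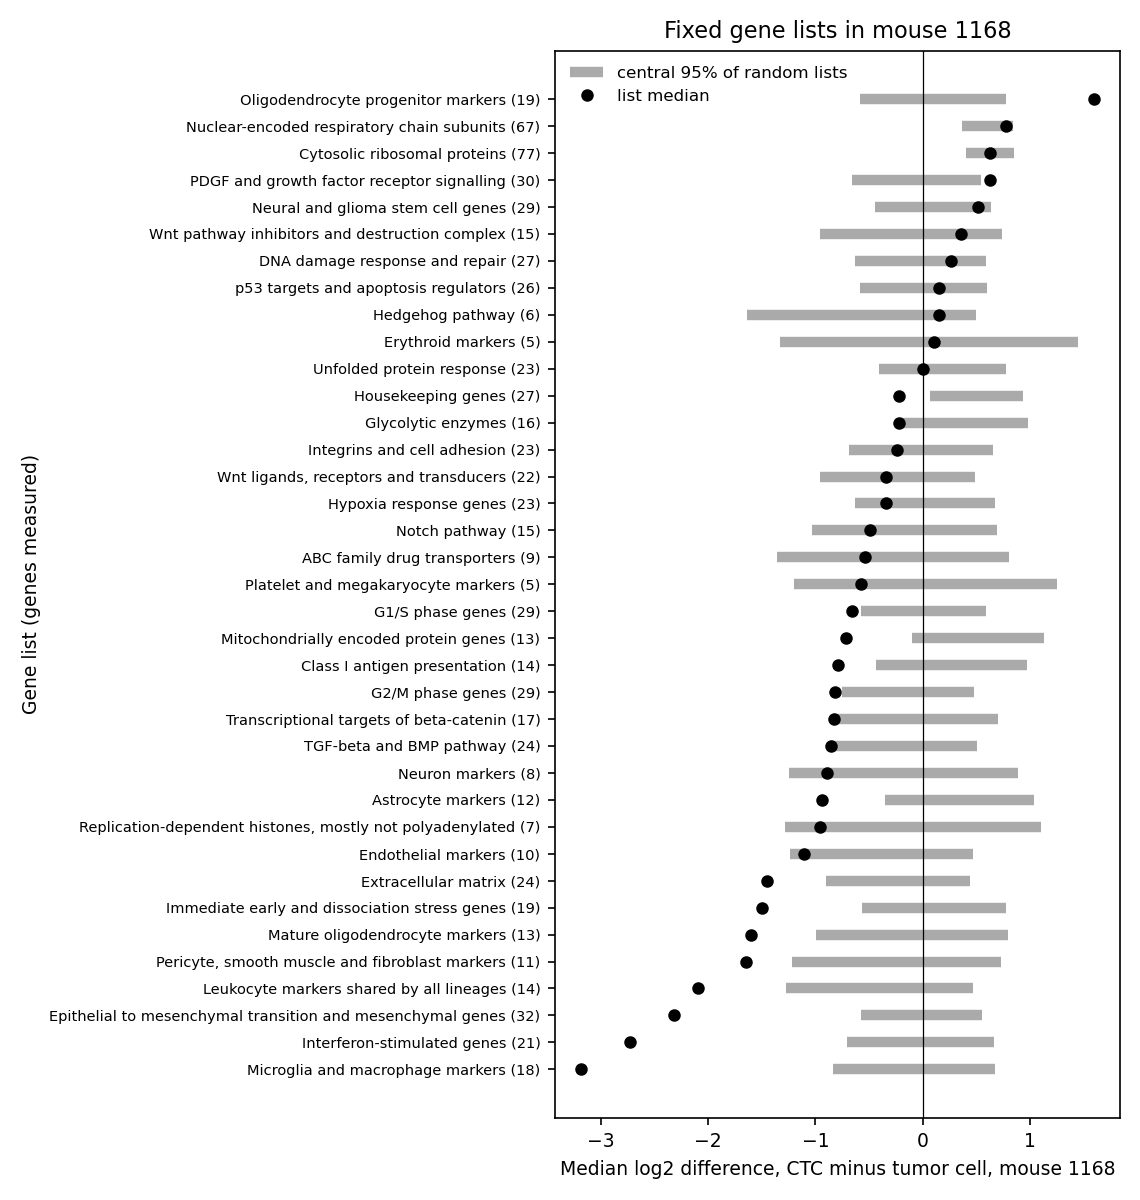
Points show the median log2(FPKM + 1) difference, CTC minus tumor cell, of each fixed list with at least 5 measured genes in mouse 1168, and gray bars the central 95% of 10000 random lists matched on expression. The oligodendrocyte progenitor list lies highest at 1.60 and the microglia and macrophage list lowest at -3.19.

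Cell cycle genes were also lower in the CTC of mouse 1168, with medians of -0.66 for G1/S genes and -0.82 for G2/M genes. The cyclin gene Ccna2 was at 1.62 FPKM against 18.2, the licensing gene Mcm4 at 5.31 against 17.9 and the proliferation marker Mki67 at 1.39 against 3.14, while the kinase gene Ttk was higher, by 2.75 on the log2 scale. The medians lay at percentiles 1.06 and 1.43 of random lists. In mouse 1157 they went the other way, at 0.82 and 0.56, and in mouse PDGF1 they were -1.12 and -1.10. The median of all genes measured was -0.63 in mouse 1157 and -1.165 in mouse PDGF1. In mouse PDGF1 the cell cycle lists thus did not stand apart from the other genes.

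The Wnt lists went different ways in mouse 1168. Ligands and receptors had a median of -0.34 (percentile 43.2), inhibitors 0.36 (percentile 84.5) and beta-catenin targets -0.82 (percentile 2.69). Among the targets Ccnd1, cyclin D1, was at 244 FPKM in the CTC against 25.2, Axin2, a feedback inhibitor, at 0.291 against 1.32, and Nkd2 at 0 against 14.3. Ctnnb1, which encodes beta-catenin, was at 34.6 against 50.1. Stem cell genes had a median of 0.52 (percentile 93.1), with Sox2 at 129 against 64.8 FPKM, Nes at 21.4 against 6.56 and Aldh1a1 at 0.0510 against 41.4.

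The cells of mice 1157 and PDGF1 held few of these transcripts. Sox2 was at 0.570 and 0.418 FPKM in the CTC and the tumor cell of mouse 1157 and at 0.0746 and 0.520 in those of mouse PDGF1, and Vim was at 1.26, 4.62, 0.608 and 0.679 in the same order. The CTC of mouse 1157 held some genes at high FPKM, among them Ndufs6 at 8653, Eef1a1, a translation factor, at 1217, Psmb8, a proteasome subunit, at 740, Hes6 at 659, Rspo1, a Wnt agonist, at 69.5 and Ccnd1 at 38.7. In its tumor cell Rspo1 was at 9.42 and the other 5 were under 10. In mouse PDGF1 the mitochondrially encoded genes were lower by at least 1 in the CTC for 12 of 12 measured. Their median of -3.81 lay below all random lists, with the limit on such percentiles in this mouse given above. Of all genes measured in that mouse, 1505 of 2522 were lower in the CTC by at least 1. The named genes of highest FPKM in that CTC were Mir21b, Rep15 at 88.0 and Dnm3 at 81.3.

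Of the single blood marker genes, Ptprc, the leukocyte common antigen, was at 0.623, 0.586 and 0.730 FPKM in the CTCs of mice 1157, 1168 and PDGF1. Hbb-bs, a globin gene, was at 0, 0.182 and 0, and Ppbp, a platelet gene, at 0.167, 0 and 0, while the vessel gene Pecam1 was at most 0.407. Other genes of blood lineages were higher in single CTCs: Lyz2 was at 174 in that of mouse 1168 and Laptm5, a leukocyte gene, at 9.80 in that of mouse 1157. The integrin gene Itga2b, a platelet marker, was at 68.0 in the CTC of mouse 1168 against 6.09 in its tumor cell. The astrocyte gene Gfap was at most 0.609 in any of the 6 cells, and the epithelial gene Epcam at most 2.24. Of other single genes, Prom1 was at most 1.90, Trp53 at most 1.52 and Cdkn2a at most 2.56.

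**Figure D3:**
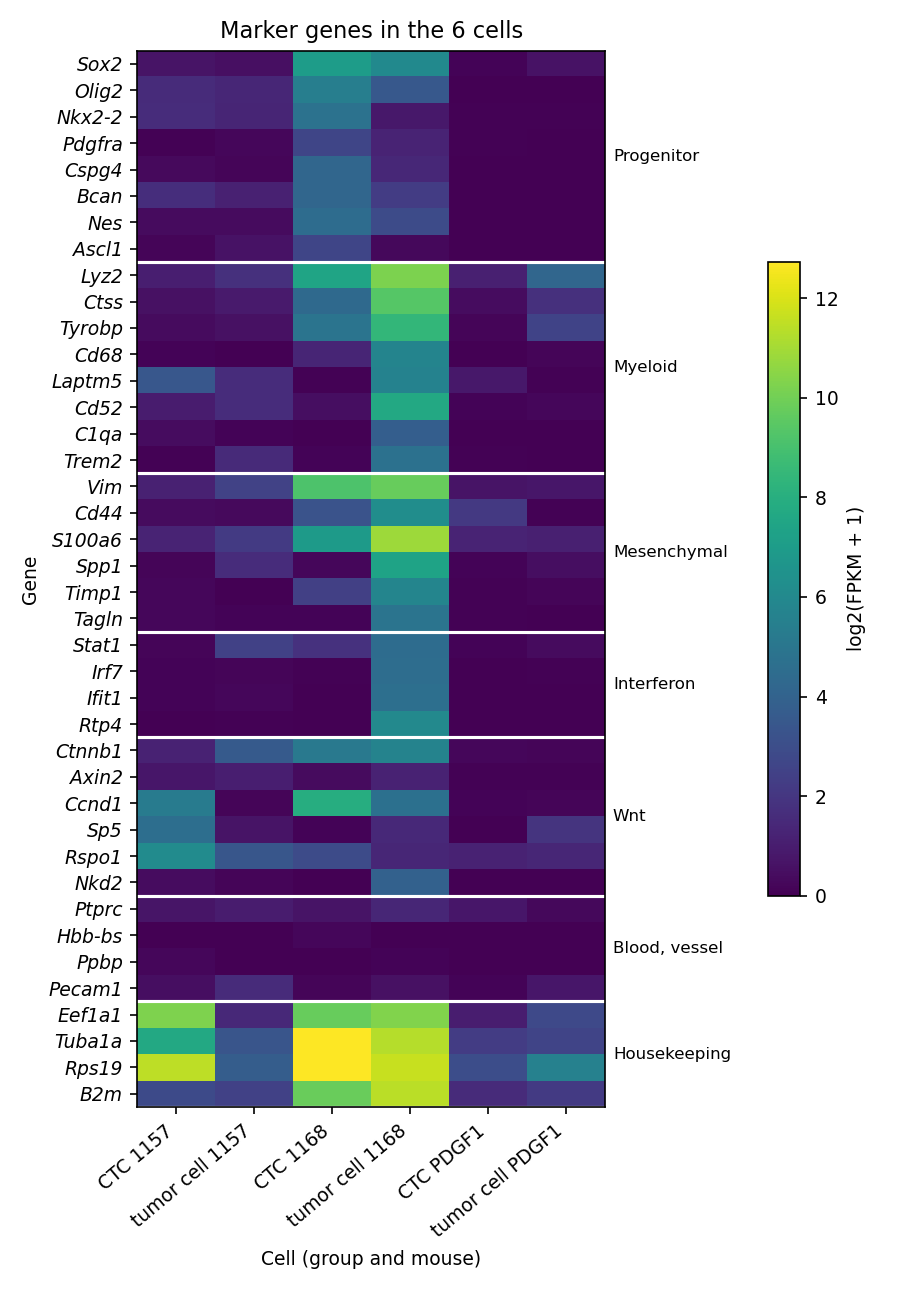
Each row is a gene and each column a cell, with color for log2(FPKM + 1). Progenitor genes such as Olig2 (42.5 FPKM) are highest in the CTC of mouse 1168 and myeloid genes such as Lyz2 (1202 FPKM) in its tumor cell, with low values for most genes in the other 4 cells.

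Y-linked genes were present in both cells of mouse 1168, with Ddx3y at 11.6 and 22.6 FPKM, Eif2s3y at 51.9 and 18.1, Kdm5d at 2.64 and 1.44 and Uty at 7.28 and 0.975 in the CTC and the tumor cell. Xist, the RNA of the inactive X chromosome, was at most 0.281 in any cell. In the other 4 cells all Y-linked genes were at most 0.716, a level at which most mRNAs were low too.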

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

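The rescaling over named protein-coding genes, the count above the receptor level and the paired test of detected genes were chosen after the data were seen, and the other alternatives before. The count of 0 genes by limma held under 18 of 19 alternatives, and the mouse as a replicate block gave 1. Of 151 named genes in 2797 combinations with an alternative, 1 passed the threshold and 264, in 84 genes, had the opposite sign to the unblocked fit with a pseudocount of 1. The number of lists was 2 with a pseudocount of 0.1, 7 with no filter (2 higher, 5 lower in CTCs), 6 at a mean FPKM of 5 or more (1 higher, 5 lower), 2 with each cell rescaled to the same total, 3 with no variance trend, 2 with the replicate block and 3 over named protein-coding genes, and from 0 to 2 with a mouse or cell left out. The interferon, mesenchymal and microglia lists were lower under both filters (camera, adjusted p = 0.0151, 0.0278 and 0.0278 with none, 0.00507, 0.00267 and 0.00267 at 5). Both filters admit genes that are high in 1 cell only, and the shift of these lists was largest in mouse 1168. In mouse 1157 interferon genes had 1 higher and 1 lower by at least 1 of 5, mesenchymal 0 and 5 of 9, and microglia 2 and 3 of 6. In mouse PDGF1 these were 0 and 2 of 2, 3 and 1 of 7, and 0 and 3 of 3. The mitochondrially encoded genes were lower at 5 (0.00822), with no trend (0.0205), over named protein-coding genes (0.0234) and without the tumor cell of mouse 1157 (0.00875). Under quantile normalization, with or without the block, they alone passed. The mitochondrially encoded genes passed under none of the other alternatives. In the unblocked fit with a pseudocount of 1 they did not pass (camera, adjusted p = 0.291). There their adjusted p was 0.961 without mouse PDGF1 and 0.955 without the tumor cell of that mouse. The settings that called them were not refitted without that cell, so whether those calls depended on it was not tested. The ribosomal protein list passed under 14 of 19 alternatives, with adjusted p (camera) from 6.11e-10 to 0.772, and its direction turned without mouse 1157 (0.730). Genes that differed the same way in all 3 mice numbered 177 with a pseudocount of 0.1 (54 higher, 123 lower in CTCs), 5 with a pseudocount of 5 (4 higher, 1 lower), 18 at a mean FPKM of 5 or more (12 higher, 6 lower), 272 with cells rescaled to the same total (29 higher, 243 lower), 28 with quantile normalization (12 higher, 16 lower) and 333 over named protein-coding genes (22 higher, 311 lower), and 199 to 398 in the 2 mice left when 1 was left out, where fewer mice must agree. The difference in detected genes turned to 41.7 at 5 FPKM and to 224 at 10 FPKM, was -3101 at 0.1 FPKM, and lay between -1547 and -1379 with a mouse left out. Above the receptor level of each cell, which was lower in the CTC of each mouse, it turned to 812, higher in the CTC in 3 of 3 mice. Over named protein-coding genes, rescaled, the difference in detected genes was -2279, with mouse PDGF1 turned (11674 against 11609). Rescaling to the same total moved the median difference of all genes from -0.06 to -0.79, and over named protein-coding genes it was -1.24. Except where fewer mice must agree, the cause was not tested. With the mouse as a block the difference in detected genes was -1435 (exact paired test, p = 0.25), and the replicate block changed no other call. Where 1 cell of a group was left out, the variance was pooled over the groups. Depth is unknown, so a gene listed at 0 or near it cannot be called absent.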

Other observations

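The tests of transcript loss in the CTC of mouse 1157 alone, of wider capture in the tumor cell of mouse 1168 and of a fixed share between its libraries were chosen only after the result was seen, and the others before. Of those others, the second myeloid list, the rescaling and the receptor level count were still added after the data had been examined. Beyond the progenitor genes, the CTC of mouse 1168 held Igfbp2, a binding protein of insulin-like growth factors, at 343 FPKM against 7.46 in the tumor cell. Aldoc, a glycolytic enzyme of astrocytes and progenitors, was at 613 against 30.9, and Fabp7, a fatty acid carrier of radial glia, at 2346 against 1059. Bmp7 was at 13.4 against 1.03, Lin28b, a regulator of small RNAs in early development, at 6.45 against 0.167, and Mgmt, which repairs alkylated DNA, at 49.1 against 6.09. Astrocyte genes as a list went the other way (median -0.94), with S100b at 108 against 364 and Apoe at 278 against 664. The tumor cell of mouse 1168 had Mir369 at 60430 FPKM, which was listed at 0 in the other 5 cells. This gene is annotated only from 109743418 to 109743496 on chromosome 12. FPKM divides by length, so few fragments can give a high value for so short a gene, and read counts are unknown.

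In the 4 cells of mice 1157 and PDGF1 fewer genes reached 1 FPKM than in mouse 1168. A count asked whether a few abundant rows had only diluted the rest. The number of named protein-coding genes above the 99th percentile of receptor genes in the same cell would then be similar, given ample depth. The highest of the 4 cells reached 0.277 of the lower mouse 1168 cell (2481 against 8958 genes). At limited depth, dilution also leaves fewer fragments of mRNA and so fewer genes above background. Depth is unknown here, so this count cannot decide. After rescaling over named protein-coding genes the ratio at 1 FPKM was 1.69, the outcome set beforehand for dilution, but the rescaling lifted background too and the ratio was set aside after it was seen. A candidate explanation is signal not from mRNA, since receptor genes took at least 5.00 times the share of coding FPKM that they took in mouse 1168, though against an even spread over genes they were at 66.3% in the CTC and 42.1% in the tumor cell of mouse PDGF1, 12.4% in the tumor cell of mouse 1157 and 1.68% in its CTC, where this background was small. Transcripts lost gene by gene may add to this in the CTC of mouse 1157. There the SD of log2 ratios over 472 abundant genes was 3.54 times that between the mouse 1168 cells. These genes were taken at 100 FPKM or more in both cells of mouse 1168. That choice holds the SD between those cells down, so the ratio gives little support. The lowest of the 4 cells was at 1.20, under the bound of 1.5 set beforehand. In that cell 0 of the 472 genes reached 100 FPKM and 37.5% were under 1, so that test was also set aside after it was seen. Loss and dilution stay open, as does a difference between the mice.

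Myeloid genes were higher in the tumor cell of mouse 1168 than in its CTC. RNA of a myeloid cell in that library could account for it: of 42 genes of a second myeloid list present in the table, 23 were at 1 FPKM or more in the tumor cell and 9 in the CTC, and 54.8% lay at percentile 100 of random lists with the same CTC levels, whose mean was 34.6% (1 of the 45 genes written for the list is also in a fixed list). Wider capture would miss genes in the CTC whatever they encode, yet of 30 microglia, macrophage and leukocyte genes at 1 FPKM or more in the tumor cell 22 were under 1 in the CTC, 73.3% against a mean of 19.1% for random lists of the same tumor cell FPKM (percentile 100), and so were 16 of 23 genes of the second list, 69.6% against 20.9% (percentile 100), which argues against it as the whole cause; this test replaced one on marker lists that are silent in such cells. Pericyte and fibroblast genes (8 of 10 under 1 in the CTC) and mesenchymal genes (17 of 32) were also often under 1 there, which a myeloid cell alone need not bring, and the library also held Sox2 at 64.8 FPKM, so RNA of several other cells, a tumor cell that expresses such genes and a difference in handling all stay open. In mouse PDGF1 the second list had 4 genes higher in the CTC and 3 lower by at least 1 while the fixed microglia list had 3 of 3 lower, and in mouse 1157 the second list had 2 higher and 1 lower.

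The CTC of mouse 1168 held some myeloid genes at lower FPKM. A fixed share of the tumor cell library read as the CTC would give 1 ratio for all of them, yet over the 6 myeloid and leukocyte genes at 50 FPKM or more in the tumor cell the CTC held from 0.186% for Cd52 to 14.5% for Lyz2, an SD of 2.27 on the log2 scale, which argues against it. These 6 genes replaced a first choice of genes that had left out Lyz2. No biological explanation was tested.

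The 6 cells can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, all 10 splits gave at least the real count of 0, as any split must, so that comparison decides nothing. The highest other split gave 327, with the CTC of mouse 1157 beside both cells of mouse 1168. These are the 3 cells with the largest share of FPKM in named protein-coding genes, which points to a structure of the samples. For lists, 8 of the 10 splits gave at least the real count of 1, and the highest other gave 3. Only 4 splits part the cells of every mouse as the real one does, the real one included, and these gave 0 genes and 1 list each.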
